A study of Mus musculus with 32 samples.

How the data were processed

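Total RNA from neuroretina and from RPE/choroid, the retinal pigment epithelium with the vascular layer beneath it, was hybridised to 32 Affymetrix mouse arrays. Young and aged mice that were either wild type (WT) or lacked complement factor H (Cfh-/-) gave 8 groups of 4 arrays, which the series' design text describes as 4 biological replicates per group. RNA was isolated with TRIzol and spin columns and labelled with biotin, per the labels' protocols. The deposited table holds intensity values on a linear scale, from 5.8 to 16719.9, and per the submitters' processing notes the authors used Affymetrix Expression Console 1.1. The summarisation and normalization algorithm run in that software was not given in the sources used here. Array medians were between 89.5 and 104.7, and arrays of one group correlated at 0.972 to 0.9965 across probe sets. The scale was settled from the values, and the number of arrays limits the precision of every comparison.

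The table held 35556 probe sets. A block of 6612 control probe sets, recognised by their identifiers lying below those of the annotated probe sets, was left out of the tests, and this boundary was chosen after the table had been seen. The remaining 28944 were tested. Gene names came from the platform's annotation table: 21789 probe sets had 1 gene symbol, 1621 had several and 5534 had none, and no gene was named from a probe set with several symbols. Of those with 1 symbol, 21698 matched the gene table of the mouse assembly GRCm38.p6 through their gene identifier, and 0 symbols changed. That gene table was used for names and for which genes neighbour each other. In total 19938 distinct symbols were measured. Values identical to those of another probe set in every array were found for 702 tested probe sets. No tested probe set was named Cfh, and 1 was named Cd59a. The number of columns with per-sample values left unused was 0.

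Because the values were linear, they were taken to log2(value + 1), a pseudocount of 1, and fold changes are on that scale, which understates changes of dim probe sets. Each contrast was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, empirical Bayes moderation with a constant prior and a two-sided test, and p-values were adjusted by the Benjamini-Hochberg method over the 28944 probe sets of the contrast. The threshold was an adjusted p of 0.05. For each tissue, 5 contrasts were taken from a fit of its 16 arrays with 12 residual degrees of freedom: Cfh-/- against WT at each age, aged against young in each genotype, and the interaction of genotype with age. A fit of all 32 arrays, with 24 residual degrees of freedom, gave the interaction of genotype with tissue at each age and the difference between tissues in young WT mice. Tissues came from mice that the labels do not link across arrays, so this fit treats all arrays as independent. The test designs, the gene lists, the rule for named genes and the alternatives, apart from those named below as added, were fixed before the data were examined.

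Named genes were taken by a rule. For each contrast the 12 genes with the largest increase and the 12 with the largest decrease were taken among those past the threshold whose groups did not overlap in any array. Where fewer than 5 genes passed, the 10 with the smallest p were given as values. Cfh and Cd59a were always to be named, with every passing complement gene and up to 4 passing members of each list. For lists, Cfh and Cd59a, a gene with several probe sets was represented by the brightest. Genes named for their change or their p were represented by the probe set with the smallest p of the contrast, so that the probe set of Trdn and of Hmcn1 differed between contrasts. Of 39 lists of complement genes, ocular and immune cell types and cellular pathways, 38 had at least 4 measured genes and were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, in the 10 contrasts within a tissue. Camera p-values were adjusted over the 38 lists of a contrast.

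The alternatives were quantile normalization, leaving out dim probe sets, an intensity trend with robust variance, the compared groups alone, the replicate number as a block, array weights, a pseudocount of 16, a covariate for carry-over of the other tissue, and leaving out each array in turn. After the data had been seen, fits without arrays read as male from Xist and Y-linked probe sets and fits without a set of probe sets that stood apart in aged WT arrays were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

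The fits were tested on simulated data for each contrast, drawn from the observed means and spreads of the 28944 probe sets with known changes added to some of them. For aged Cfh-/- against WT neuroretina, 37.3% of 67 changes of 0.5, 89.6% of 67 changes of 1 and 98.5% of 66 changes of 2 on the log2 scale were recovered. For aged against young WT RPE/choroid the shares were 22.4%, 82.1% and 98.5%, and for the neuroretina interaction 8.96%, 70.1% and 97.0%. Unchanged probe sets were 7 of 157, 5 of 140 and 11 of 128 calls in these simulations. The largest shares elsewhere were 11 of 153 calls for young RPE/choroid between genotypes and 10 of 151 with age in Cfh-/- RPE/choroid. A shifted gene list was called in each of the 10 contrasts within a tissue, and 1 unshifted list was called, with age in Cfh-/- neuroretina. Genes were drawn independently of each other. The simulations therefore do not show how often lists are wrongly called where genes vary together, as in the real arrays.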

Results

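Gene expression was measured on 32 arrays of neuroretina and RPE/choroid from young and aged mice, all labelled as C57BL/6J background. Mice were wild type (WT) or lacked complement factor H (Cfh-/-), the main soluble inhibitor of the alternative complement pathway. Each of the 8 groups held 4 arrays of 4 biological replicates. Array medians lay between 89.5 and 104.7 intensity units, and the number of arrays limits the precision. The series title names lower neuroretinal expression of Cd59a in aged Cfh-/- mice as its subject. Values are given as mean ± SD of the intensity and as log2 fold change ± SE from limma, with 4 arrays per group throughout.

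The targeted gene was to be reported before any other, but no tested probe set carried Cfh as its single gene symbol. Its own transcript was therefore not analysed here by name. Probe set 10358339, which has no single gene symbol and was chosen after its values were seen, was lower in Cfh-/- than in WT in each tissue and at each age. In young neuroretina it read 487 ± 57.6 in WT and 45.8 ± 4.77 in Cfh-/-, and in aged neuroretina 698 ± 20.8 and 42.2 ± 5.45. In RPE/choroid the values were 2846 ± 407 and 415 ± 66.8 in young mice and 2962 ± 166 and 632 ± 160 in aged mice. The 4 log2 fold changes were -3.38, -4.03, -2.78 and -2.26, with limma adjusted p between 4.10e-13 and 4.30e-06. Another unnamed probe set, 10608654, chosen in the same way, was lower in the same 4 contrasts, with log2 fold changes of -2.01, -2.20, -2.26 and -1.99. Xist and Y-linked probe sets read as male in 2 of 4 aged Cfh-/- neuroretina arrays and 3 of 4 aged Cfh-/- RPE/choroid arrays, and in 0 arrays of the other 6 groups.

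Cd59a encodes a membrane-anchored inhibitor of the terminal complement pore. In neuroretina its intensity was 1306 ± 62.6 in young WT, 1308 ± 209 in young Cfh-/-, 2179.6 ± 96.2 in aged WT and 1423 ± 87.1 in aged Cfh-/- mice. In aged neuroretina Cd59a was lower in Cfh-/- than in WT, with a log2 fold change of -0.62 ± 0.10 (limma adjusted p = 0.00914), and all 4 Cfh-/- arrays lay below all 4 WT arrays. In WT neuroretina it rose with age by 0.74 ± 0.10 (limma adjusted p = 0.000929), whereas the change in Cfh-/- neuroretina was 0.13 ± 0.10 (limma adjusted p = 0.965). The interaction of genotype with age, -0.61 ± 0.14, had an unadjusted limma p of 0.000551. It did not pass the threshold over all probe sets (limma adjusted p = 0.389), so at that threshold the effect of genotype was not shown to differ between ages. In young neuroretina the genotypes differed by -0.01 ± 0.10 (limma adjusted p = 0.999).

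RPE/choroid held less Cd59a than neuroretina. Its intensity there was 310 ± 97.2 in young WT, 223 ± 128 in young Cfh-/-, 331 ± 76.3 in aged WT and 187 ± 35.2 in aged Cfh-/- mice. The genotype differences of Cd59a in RPE/choroid, -0.61 ± 0.35 in young and -0.81 ± 0.35 in aged mice, did not pass (limma adjusted p = 0.749 and 0.695). The interaction of genotype with tissue for Cd59a in aged mice was 0.20 ± 0.38 (limma adjusted p = 1.00). For the call in aged neuroretina, the limma adjusted p ranged from 0.00262 to 0.202 over 18 alternatives, with log2 fold changes from -0.64 to -0.57. The Cd59a call ended without aged Cfh-/- replicate 2 (limma adjusted p = 0.0552) and without the male arrays (limma adjusted p = 0.202).

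**Figure D1:**
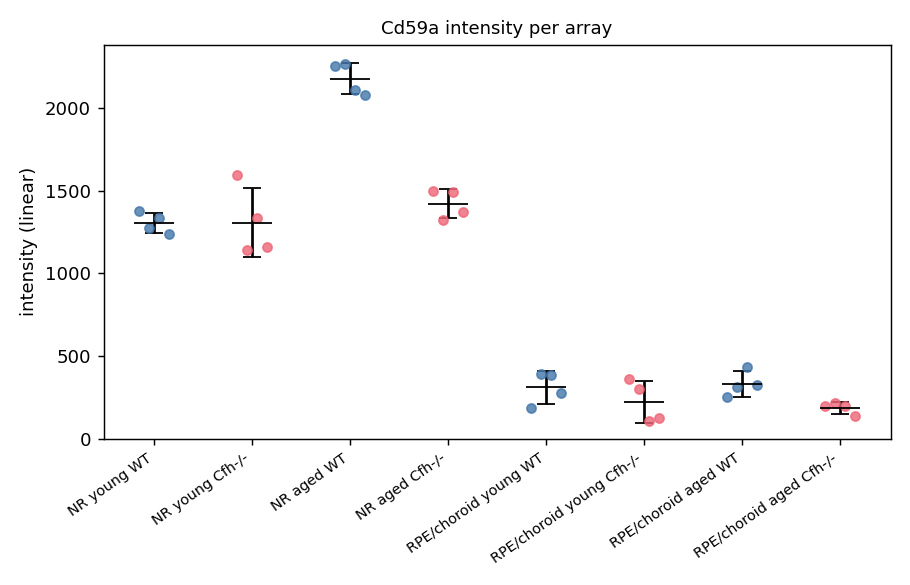
Cd59a array intensity (linear scale) in each of the 8 groups of tissue, age and genotype; points are single arrays and bars the mean with SD of 4 arrays. In neuroretina the aged WT arrays average 2179.6 and the other groups 1306, 1308 and 1423.

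Complement genes measured by name, other than Cd59a, passed in no genotype contrast. Of the 14 measured complement regulators in aged neuroretina, 0 rose and 1 fell, that being Cd59a, and 1 fell adjusted over the list alone. The list as a set lay lower in Cfh-/- mice (camera adjusted p = 0.0207, adjusted p = 0.149 with an estimated correlation), and this call ended with 3 of 8 single arrays left out (camera adjusted p up to 0.105, without aged Cfh-/- replicate 2). In WT neuroretina with age the same list lay higher (camera adjusted p = 0.0109, adjusted p = 0.0889 with an estimated correlation), with 1 member past the threshold over all genes and 2 adjusted over the list alone. That call ended without young WT replicate 1 (camera adjusted p = 0.0621).

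In young neuroretina Mcm6, a subunit of the replicative DNA helicase, was lower in Cfh-/- mice. Its intensity was 132 ± 14.7 in WT and 59.6 ± 3.90 in Cfh-/-, a log2 fold change of -1.13 ± 0.12 (limma adjusted p = 0.000251). Arpc5, a subunit of the actin-nucleating Arp2/3 complex, was lower too (-1.13 ± 0.16, limma adjusted p = 0.011), a call that ended with 5 of 8 single arrays left out (limma adjusted p up to 0.0779). Together with the unnamed probe sets described above, these were the 4 probe sets past the threshold, and 1050 had an unadjusted p under 0.05. Further genes with the smallest p were Timm17a (-0.42), Rabif (-0.38), A930024E05Rik (0.45), Ggps1 (-0.47), Scarna17 (-0.56), Plp2 (0.42), Rnu3a (-0.48) and Olfr97 (-0.66), none past the threshold in limma. As sets, lens crystallins lay lower in Cfh-/- mice (camera adjusted p = 3.16e-07) and rod photoreceptor genes higher (camera adjusted p = 0.000161), with adjusted p = 0.792 and 0.825 with an estimated correlation and 0 members past the threshold over all genes or adjusted over the list alone. Young WT replicate 1 stood apart on the crystallins, with a mean log2 intensity of 8.22 against 7.41 to 7.50 in the other 3, and without it the list's camera adjusted p was 0.0236. The rod call ended without young WT replicate 4, which read 11.63 over rod genes against 12.09 to 12.15 (camera adjusted p = 0.286).

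In aged neuroretina Pttg1, the securin that restrains separase, was the gene with the largest increase in Cfh-/- mice. Pttg1 read 77.7 ± 16.3 in aged WT and 1090 ± 104 in aged Cfh-/- arrays, and 917 ± 145 and 980 ± 105 in young WT and Cfh-/- arrays. Its log2 fold change in aged mice was 3.81 ± 0.14 (limma adjusted p = 2.04e-11). Catspere2, of a family of sperm calcium channel subunits (2.83), 5830417I10Rik (1.61) and Gm10590 (1.02) rose as well. Lower in Cfh-/- mice were Nmnat1, the nuclear enzyme of NAD synthesis (-1.46 ± 0.14), Cerkl, a ceramide kinase-like gene linked to inherited retinal degeneration (-1.13 ± 0.12), Rbp7, a cellular retinol-binding protein (-1.07 ± 0.12), Lyrm7, a mitochondrial respiratory chain assembly factor (-1.29 ± 0.13), and Mcm6 (-1.19 ± 0.12), with limma adjusted p between 1.44e-05 and 0.000106. The microRNA gene Mir680-2 (-1.88) and Tmem144 (-0.65) also fell. Pttg1, Catspere2, 5830417I10Rik, Gm10590, Nmnat1 and Rbp7 belong to a set of 26 probe sets that stood apart in aged WT arrays of both tissues.

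Further changes in the same tissue were called in limma but ended with 3 to 7 of 8 single arrays left out. They were increases of Itgav, an integrin alpha chain (0.50, limma adjusted p up to 0.0723 with an array left out), and Pgm1, a phosphoglucomutase (0.82, up to 0.104), and decreases of Gpnmb, a glycoprotein of melanosomes and macrophages (-1.08, up to 0.0985), Ube2t (-0.78, up to 0.0983), Anks1b (-0.69, up to 0.114), Ppp1r3a (-0.79, up to 0.209) and the chemokine gene Ccl17 (-0.66, up to 0.155). Apart from that of Gpnmb, these calls also ended without the male arrays, as did that of Tmem144 (limma adjusted p = 0.124). Gpnmb was the 1 of 14 melanin synthesis genes that passed, over all genes and adjusted over the list alone, and that list lay lower as a set (camera adjusted p = 8.07e-05, adjusted p = 0.382 with an estimated correlation), a call that ended without aged WT replicate 1 (camera adjusted p = 0.0658). Rpe65, the isomerohydrolase of the pigment epithelium, read 1024 ± 96.5 in aged WT neuroretina and 723 ± 398 in aged Cfh-/- neuroretina, a measure of carry-over of the neighbouring tissue. Immediate early genes lay higher as a set (camera adjusted p = 8.07e-05, adjusted p = 0.382 with an estimated correlation), with 0 members past the threshold over all genes and 1 adjusted over the list alone. Mcm6 was the 1 member of the cell cycle list that passed on either count.

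In all, 54 probe sets passed in aged neuroretina, 22 higher and 32 lower, and 27 of them had no single gene symbol. Counting probe sets with identical values once, 47 passed. The balance of directions depended on the setting. It was 20 higher and 14 lower, 34 in all, without the male arrays, and 20 and 15, 35 in all, when the compared groups were fitted alone. It was 6 and 21, 27 in all, without the 26 probe sets that stood apart in aged WT arrays of both tissues, and 35 and 93, 128 in all, with array weights. The genotype by age interaction in neuroretina passed for 21 probe sets, 11 higher and 10 lower. Among them Pttg1 (3.71 ± 0.20), 5830417I10Rik (1.61 ± 0.13) and Gm10590 (0.98 ± 0.12) had positive terms, and Nmnat1 (-1.50 ± 0.19), Cerkl (-1.34 ± 0.17) and Rbp7 (-1.27 ± 0.17) negative ones, with limma adjusted p between 1.50e-08 and 0.00257. Catspere2 (3.00), Mir680-2 (-1.94) and Lyrm7 (-1.17) passed too, of which Catspere2 and Lyrm7 did not without the male arrays (limma adjusted p = 0.0509 for both). The interaction count was 12 without the male arrays, 2 without the 26 probe sets and 61 with array weights.

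**Figure D2:**
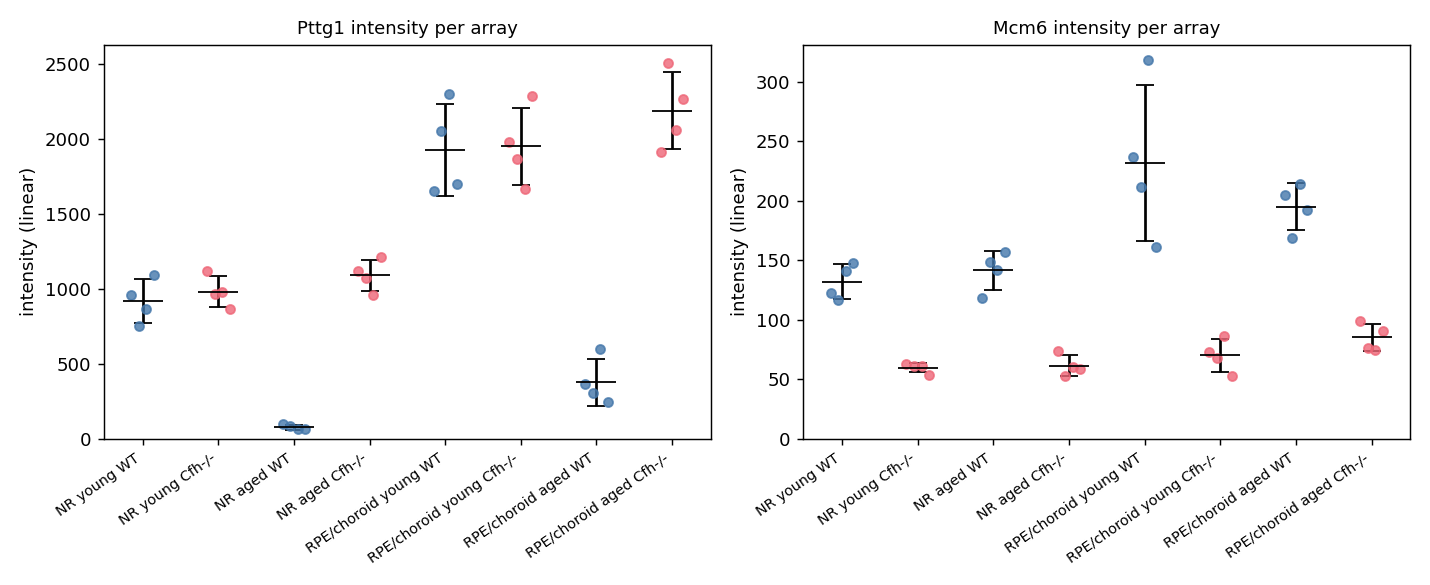
Array intensity (linear scale) of Pttg1 and Mcm6 in the 8 groups; points are single arrays and bars the mean with SD of 4 arrays. Pttg1 averages 77.7 in aged WT neuroretina against 1090 in aged Cfh-/- neuroretina, and Mcm6 is lower in Cfh-/- than in WT in each tissue and age group.

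With age, WT neuroretina gained expression of Glb1l3, a member of the beta-galactosidase family, from 379 ± 63.0 to 1852 ± 197 (2.29 ± 0.12, limma adjusted p = 6.22e-09). Bst1, a cyclic ADP-ribose forming ectoenzyme (1.51 ± 0.10), Cerkl (1.54 ± 0.12), Csrp3, a muscle LIM protein (1.36 ± 0.17), Rdh9, a retinol dehydrogenase (1.57 ± 0.27), and Dnah7b, an axonemal dynein heavy chain (1.28 ± 0.12), rose as well, with limma adjusted p between 1.99e-07 and 0.00835. Mir680-2 (2.15), 2410124H12Rik (1.89), Pate2 (1.55), Gm11961 (1.49) and Tmem116 (1.30) were further increases. Pttg1 (-3.55 ± 0.14), Catspere2 (-2.48), Apobec2, of the cytidine deaminase family (-1.20 ± 0.09), Aga, a lysosomal glycoprotein hydrolase (-0.89 ± 0.12), and Mthfd2, a mitochondrial folate enzyme (-0.79 ± 0.12), fell, with limma adjusted p between 9.88e-11 and 0.00177. Pttg1, Catspere2 and Aga belong to the 26 probe sets apart in aged WT arrays, and whether age is the cause of their fall was not tested.

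Several lists moved with age in WT neuroretina. Of 18 lens crystallins 3 fell, Crygb (-2.53), Crygd (-2.07) and Crygc (-1.84), and 5 fell adjusted over the list alone (camera adjusted p = 8.44e-13, adjusted p = 0.0889 with an estimated correlation). Of 14 melanin synthesis genes 2 rose, Gpnmb (1.21) and Rab38, a melanosome trafficking GTPase (0.80), and 6 rose adjusted over the list alone (camera adjusted p = 1.12e-10, adjusted p = 0.0889 with an estimated correlation). RPE and visual cycle genes also lay higher (camera adjusted p = 6.46e-05, adjusted p = 0.35 with an estimated correlation), with 0 members past the threshold over all genes and 5 adjusted over the list alone, and Rpe65 read 544 ± 203 in young and 1024 ± 96.5 in aged WT neuroretina. Young WT replicate 4 stood apart on this list (8.01 against 8.24 to 8.27), and on the crystallins young WT replicate 1 (8.22 against 7.41 to 7.50) and aged WT replicate 1 (7.03 against 6.83 to 6.86) did, as mean log2 intensities. Of 20 microglia and macrophage genes 2 rose on either count, the lysozyme gene Lyz2 (1.47) and the cathepsin gene Ctss (0.53) (camera adjusted p = 1.61e-05, adjusted p = 0.0889 with an estimated correlation). Aged WT replicate 1 stood apart on this list, with a mean log2 intensity of 6.79 against 6.50 to 6.52, and without it the list's camera adjusted p was 0.0062. The Lyz2 and Ctss calls ended with 7 and 5 of 8 single arrays left out (limma adjusted p up to 0.131 and 0.162). Heat shock and unfolded protein response genes lay lower (camera adjusted p = 3.24e-05, adjusted p = 0.135 with an estimated correlation), with the stress transcription factor Atf4 (-0.49) the 1 of 21 members past the threshold on either count, a call that ended with 5 single arrays left out (limma adjusted p up to 0.0900). In all 138 probe sets passed, 97 higher and 41 lower, of which 25 belong to the 26 probe sets apart in aged WT arrays. The count was 95 without those 26, 81 without young WT replicate 3 and 89 without aged WT replicate 2. It was 76 with the compared groups alone and 455 with array weights. With the covariate for carry-over of the other tissue it was 103, with 62 higher and 41 lower, so the number of increases depended on this setting. Whether the melanin, RPE and crystallin lists moved through age or through a change in the dissection was not tested.

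In Cfh-/- neuroretina Glb1l3 rose with age by 2.38 ± 0.12, Pate2 by 1.65 ± 0.20, Dnah7c by 1.36 ± 0.17, Csrp3 by 1.35 ± 0.17 and Dnah7b by 1.09 ± 0.12, with limma adjusted p between 1.04e-08 and 0.000945. Tec, a non-receptor tyrosine kinase (1.06), Clic6, a chloride channel family member (0.99), and Ly75, an endocytic receptor of dendritic cells (0.97), also rose. Dio2, which activates thyroid hormone (-1.06 ± 0.12), Apobec2 (-0.96 ± 0.09) and Dynlrb2, a dynein light chain (-0.76 ± 0.09), fell, with limma adjusted p between 0.000179 and 0.000653. Of 20 microglia and macrophage genes 0 passed over all genes or adjusted over the list alone, and the list lay higher as a set (camera adjusted p = 0.00509, adjusted p = 0.555 with an estimated correlation). In all 42 probe sets passed, 37 higher and 5 lower. The WT and Cfh-/- comparisons with age, which share no arrays, had 31 increases in common against 0.124 expected for independent lists and 3 decreases against 0.00708. The count was 25 without young Cfh-/- replicate 2, 20 without the male arrays and 168 with array weights.

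In young RPE/choroid Mcm6 was lower in Cfh-/- mice, 232 ± 65.4 in WT against 70.0 ± 13.7, a log2 fold change of -1.69 ± 0.18 (limma adjusted p = 0.000879). Dbi, an acyl-CoA binding protein, was lower too (-0.69 ± 0.10, limma adjusted p = 0.0218), a call that ended with 6 of 8 single arrays left out (limma adjusted p up to 0.121). With the unnamed probe sets described above, 4 probe sets passed, and 2103 had an unadjusted p under 0.05. Hspa1l (-1.22), Ctse (1.41), Acsf2 (0.84), Snord49b (1.53), Vat1 (0.67), Mapk14 (-0.61), Ppm1g (0.50) and Gabra5 (-0.72) had the next smallest p and did not pass in limma. RPE and visual cycle genes lay higher as a set (camera adjusted p = 2.78e-07, adjusted p = 0.403 with an estimated correlation), with 0 of 18 members past the threshold over all genes and 0 adjusted over the list alone. Cholesterol and lipid metabolism genes also lay higher (camera adjusted p = 0.000448, adjusted p = 0.161 with an estimated correlation), with 0 and 1 members past the threshold on those counts. The lens crystallin Crygd ranged from 79.9 to 4129.5 among young Cfh-/- arrays.

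In aged RPE/choroid Pttg1 was higher in Cfh-/- mice, 2186 ± 257 against 377 ± 156 in WT (2.61 ± 0.21, limma adjusted p = 1.00e-05). Ctse, the aspartic protease cathepsin E (1.91 ± 0.24), Cd5l, a protein secreted by macrophages (1.34 ± 0.18), 5830417I10Rik (1.64), Fbxw18 (1.57) and Gm10590 (1.23) were higher as well. Rbp7 (-2.24 ± 0.22), H2-M2, a non-classical MHC class I gene (-1.71 ± 0.15), Olfr1372-ps1 (-2.13), Mcm6 (-1.19 ± 0.18) and Dbi (-0.78 ± 0.10) were lower, with limma adjusted p between 2.66e-05 and 0.0087. Pttg1, 5830417I10Rik, Gm10590 and Rbp7 belong to the 26 probe sets apart in aged WT arrays of both tissues. In RPE/choroid the aged WT arrays differed from the other groups by -2.49 for Pttg1 and 2.24 for Rbp7 on the log2 scale. Trdn, the triadin of muscle calcium release (-2.91), Jchain, the joining chain of secreted immunoglobulins (-1.07), and 1 probe set of Hmcn1, an extracellular matrix protein (-1.13), were lower, and Cck, the cholecystokinin precursor (1.05), Fcrls, a microglial Fc receptor-like gene (1.43), and Gpc3, a cell surface proteoglycan (0.82), were higher. The calls of these 6 genes ended with 4 to 7 of 8 single arrays left out, with limma adjusted p of up to 0.0728 for Trdn, 0.103 for Jchain, 0.0791 for Hmcn1, 0.0697 for Cck, 0.157 for Fcrls and 0.0644 for Gpc3. The probe sets of Hmcn1 disagreed, with 1 of 77 called, 50 higher and 27 lower and the brightest at 0.12 (limma adjusted p = 0.973). All 19 of Trdn were lower, 6 of them called, with the brightest at -2.09 (limma adjusted p = 0.0192). Without the male arrays, which leaves 1 aged Cfh-/- array, the calls of 21 named genes ended in limma, and those of Pttg1, H2-M2 and Trdn held.

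Skeletal muscle genes lay lower as a set in aged Cfh-/- RPE/choroid (camera adjusted p = 6.04e-19, adjusted p = 0.201 with an estimated correlation), with 0 of 18 past the threshold over all genes and 13 lower adjusted over the list alone. Examples chosen after their values were seen are the myosin heavy chain Myh1 (-1.56), the giant sarcomere protein Neb (-1.28) and Mybpc2 (-1.43), which did not pass over all genes. Melanin synthesis genes lay higher (camera adjusted p = 1.73e-08, adjusted p = 0.201 with an estimated correlation), with 0 of 14 past the threshold over all genes and 7 higher adjusted over the list alone. Tyrp1 (0.38) and Dct (0.37), enzymes of eumelanin synthesis, and Pmel (0.46), which forms melanosome fibrils, were among those 7, chosen for mention in the same way, and did not pass over all genes. Mast cell genes lay lower (camera adjusted p = 0.00136, adjusted p = 0.201 with an estimated correlation), with 0 of 9 past the threshold over all genes and 3 adjusted over the list alone. Bipolar cell genes (camera adjusted p = 0.00212, adjusted p = 0.356 with an estimated correlation) and retinal ganglion cell genes (camera adjusted p = 0.000256, adjusted p = 0.31 with an estimated correlation) lay lower too, with 0 members past the threshold on either count. The calls of the melanin and ganglion cell lists ended without the male arrays (camera adjusted p = 0.0501 for both).

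In all 58 probe sets passed in aged RPE/choroid, 32 higher and 26 lower. The count was 32 without aged WT replicate 4, without aged Cfh-/- replicate 3 or without aged Cfh-/- replicate 4, 26, with 11 higher and 15 lower, without the 26 probe sets apart in aged WT arrays, and 14 without the male arrays, which leaves 1 aged Cfh-/- array whose spread is taken from the other groups. The genotype by age interaction in RPE/choroid passed for 16 probe sets, 10 higher and 6 lower. Pttg1 (2.59 ± 0.30), 5830417I10Rik (1.76 ± 0.25) and 1700029I15Rik (0.92 ± 0.14) had positive terms and H2-M2 (-1.53 ± 0.22) a negative one, with limma adjusted p between 0.00163 and 0.0137. The terms of the GABA receptor subunit Gabra5 (1.27), the protocadherin Pcdhb12 (-1.75) and Zmat2 (-0.87) passed, but those calls ended with 3, 10 and 12 of 16 single arrays left out (limma adjusted p up to 0.063, 0.0842 and 0.103). The calls of all 7 of these genes ended without the male arrays. The interaction count was 10 without aged Cfh-/- replicate 3, 8 without the male arrays, 0 without the 26 probe sets (limma, with 2137 probe sets at an unadjusted p under 0.05 when these are kept) and 29 with array weights.

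With age, RPE/choroid gained expression of macrophage genes in both genotypes. Lyz2 rose from 1740 ± 276 to 6549 ± 284 in WT (1.92 ± 0.11, limma adjusted p = 1.62e-07) and from 1967 ± 233 to 6839 ± 303 in Cfh-/- mice (1.80 ± 0.11, limma adjusted p = 2.94e-07). Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, rose by 4.10 ± 0.30 in WT and 3.11 ± 0.30 in Cfh-/- mice, Mmp3, the matrix protease stromelysin, by 2.75 ± 0.16 and 3.04 ± 0.16, and Serpina3n, an acute-phase protease inhibitor, by 2.60 ± 0.28 and 3.01 ± 0.28. Il7r, the interleukin 7 receptor, rose by 3.03 and 2.22, and the immune cell receptors Cd84 and Slamf7 by 2.44 and 2.34 in WT and 2.25 and 2.32 in Cfh-/- mice. Of these 7 genes the largest limma adjusted p was 0.000352. The muscle gene Trdn rose in WT by 3.34 ± 0.50 (limma adjusted p = 0.00187), with 15 of its 19 probe sets called and the brightest at 1.41 (limma adjusted p = 0.0483). Without the male arrays, which leaves 1 aged Cfh-/- array, the calls of 68 of the 74 genes named in Cfh-/- mice ended in limma, and those of Lyz2, Mmp3, Ctss, Nqo1 and Casp4 held.

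Of 20 microglia and macrophage genes, 8 rose and 1 fell in WT, and 10 rose and 1 fell in Cfh-/- RPE/choroid. Adjusted over the list alone, 11 rose and 2 fell in WT, and 13 rose and 1 fell in Cfh-/- mice. The list lay higher as a set in WT (camera adjusted p = 1.34e-12, adjusted p = 0.0194 with an estimated correlation) and in Cfh-/- mice (camera adjusted p = 7.08e-13, adjusted p = 0.0145 with an estimated correlation). Cd68, a lysosomal glycoprotein of phagocytes (2.00 in WT and 1.38 in Cfh-/-), Ctss (1.47 and 1.68) and the Fc receptor chain Fcer1g (1.33 and 1.30) were among those that rose. The members that fell, singled out after their values were seen, were the haemoglobin scavenger receptor gene Cd163 in WT (-0.79) and Csf1r, the receptor of macrophage colony-stimulating factor, in Cfh-/- mice (-0.79, with -0.08 in WT).

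Complement genes rose with age in RPE/choroid. Among 9 complement receptor genes, 4 rose in WT and 4 in Cfh-/- mice, in each case the integrin chains Itgax (2.21 in WT and 1.63 in Cfh-/-), Itgb2 (1.47 and 1.33) and Itgam (1.11 and 0.99) and the anaphylatoxin receptor C3ar1 (1.39 and 1.42). Adjusted over the list alone, 4 rose and 0 fell in WT, and 5 rose and 1 fell in Cfh-/- mice. The list lay higher in WT (camera adjusted p = 1.52e-06, adjusted p = 0.0275 with an estimated correlation) and in Cfh-/- mice (camera adjusted p = 1.56e-06, adjusted p = 0.0188 with an estimated correlation). Of 21 complement activation genes, 2 rose in WT, C1qc (1.69) and C1s1 (1.42), and 6 adjusted over the list alone (camera adjusted p = 0.00794, adjusted p = 0.154 with an estimated correlation). In Cfh-/- mice 6 of them rose, among them C1s1 (1.78), C1qc (1.29), the alternative pathway protease Cfb (1.19) and the classical pathway protease C2 (1.03), and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.44e-06, adjusted p = 0.0271 with an estimated correlation). The calls of the other passing members, C4b (0.66) and C1ra (0.73), ended with 5 and 8 of 8 single arrays left out (limma adjusted p up to 0.0769 and 0.145). Without the male arrays the call of every complement gene in Cfh-/- mice ended, while the activation and receptor lists still lay higher (camera adjusted p = 5.35e-05 and 4.50e-05). Serping1, the C1 inhibitor, rose by 0.73 in WT and 0.88 in Cfh-/- mice. The interaction did not pass for any complement gene, so these changes were not shown to differ between genotypes.

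**Figure D3:**
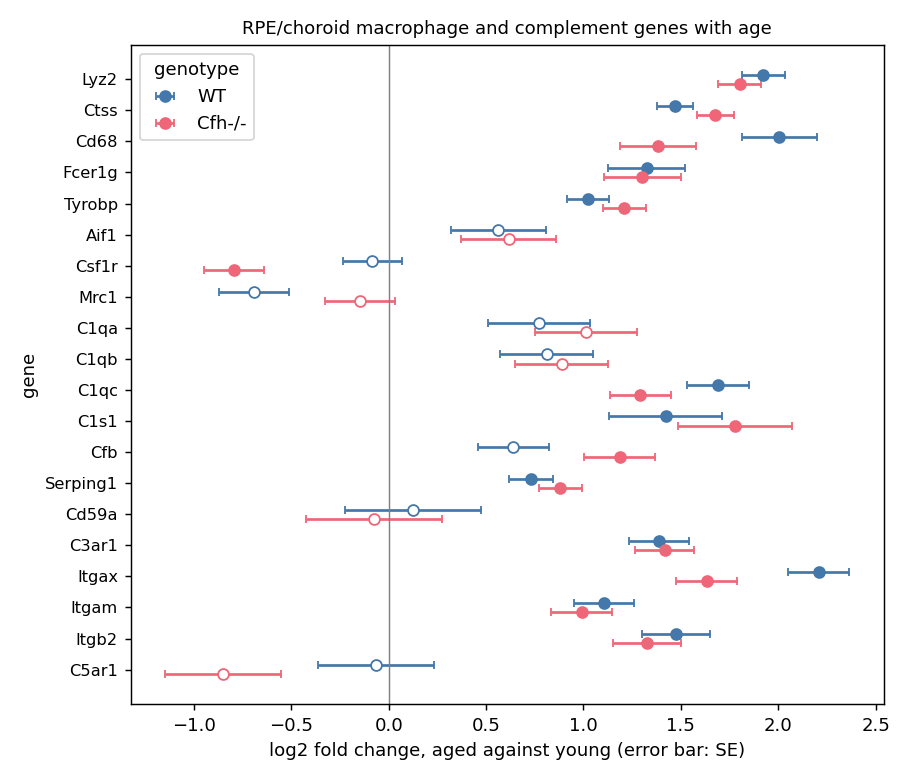
Log2 fold change with SE, aged against young RPE/choroid, of macrophage and complement genes in WT and Cfh-/- mice; filled points passed an adjusted p of 0.05 and open points did not. Lyz2, Ctss and Cd68 rose in both genotypes, and Cfb passed in Cfh-/- mice.

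T and B lymphocyte genes also lay higher in WT (camera adjusted p = 1.52e-06, adjusted p = 0.00957 with an estimated correlation) and Cfh-/- RPE/choroid (camera adjusted p = 3.43e-05, adjusted p = 0.0145 with an estimated correlation). Of 11 members 4 rose in each genotype, and 5 in each adjusted over the list alone, among them Ptprc, the leukocyte common antigen (1.42 in WT and 1.37 in Cfh-/-), and Cd3g, a T cell receptor chain (2.46 and 1.66). The Cd3g call in Cfh-/- mice ended with 5 of 8 single arrays left out (limma adjusted p up to 0.0800). Of 18 gliosis and retinal stress genes, 1 rose in WT and 6 rose and 1 fell in Cfh-/- mice, and 6 in WT and 7 in Cfh-/- mice rose adjusted over the list alone, with 1 lower in the latter. Both sets lay higher, in WT with camera adjusted p = 6.12e-05 (adjusted p = 0.0277 with an estimated correlation) and in Cfh-/- mice with camera adjusted p = 6.33e-06 (adjusted p = 0.0145 with an estimated correlation). Serpina3n was the WT member, and the one that fell in Cfh-/- mice was Gfap, the astrocyte and Mueller glia filament (-2.03).

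Genes that fell with age in RPE/choroid of both genotypes included Pappa2, a protease of insulin-like growth factor binding proteins (-2.89 ± 0.26 in WT and -2.15 ± 0.26 in Cfh-/-), and Nqo1, a quinone reductase of the oxidative stress response (-1.57 ± 0.16 and -1.43 ± 0.16), with limma adjusted p of at most 0.000451. In WT the neprilysin gene Mme (-1.57), Cldn10 (-1.54), Fcrls (-1.86) and Pttg1 (-2.42) fell, and in Cfh-/- mice Krt23 (-1.85), the cartilage protein gene Chad (-1.81) and Cldn12 (-1.42) fell. Pttg1 belongs to the 26 probe sets apart in aged WT arrays. Of 18 lens crystallins 5 fell in WT on either count, led by Crygd (-4.98) and Cryga (-4.83), and the list lay lower (camera adjusted p = 3.20e-05, adjusted p = 0.403 with an estimated correlation). The Crygd call ended without aged WT replicate 1 (limma adjusted p = 0.0611), and Crygd read 3936 ± 2255 in young and 134 ± 101 in aged WT RPE/choroid. RPE and visual cycle genes lay lower in Cfh-/- mice (camera adjusted p = 0.000173, adjusted p = 0.353 with an estimated correlation), with 3 of 18 lower over all genes and 1 higher and 8 lower adjusted over the list alone. The bicarbonate and chloride exchanger Slc26a7 was among those that fell (-0.70 in WT and -0.64 in Cfh-/-).

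In all 693 probe sets passed with age in WT RPE/choroid, 380 higher and 313 lower, and 730 in Cfh-/- RPE/choroid, 412 higher and 318 lower. The excess of increases depended on the setting, with 322 higher and 386 lower in WT and 393 and 426 in Cfh-/- mice without dim probe sets, and 388 and 377 in WT and 402 and 403 in Cfh-/- mice with the carry-over covariate. Quantile normalization gave 500 and 314 in WT and 386 and 273 in Cfh-/- mice. The comparisons use different arrays and had 178 increases in common against 5.41 expected for independent lists and 85 decreases against 3.44. As in neuroretina, both take the spread from the same fit, so the lists are not fully independent. The WT count was 454, 407 and 438 without young replicate 3, aged replicate 1 and aged replicate 2, and 431 with the compared groups alone. The Cfh-/- count was 464, 425, 446, 347 and 338 without young replicates 3 and 4 and aged replicates 1, 2 and 4, 470 with the compared groups alone, 1138 with array weights and 13 without the male arrays, which leaves 1 aged array.

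In aged mice the effect of genotype differed between tissues for 13 probe sets, 6 with a positive and 7 with a negative term for neuroretina over RPE/choroid. H2-M2 (1.68 ± 0.20), Catspere2 (2.36 ± 0.39) and Olfr1372-ps1 (2.42) had positive terms, and Ctse (-1.75 ± 0.27), Mir680-2 (-1.81 ± 0.32) and Fbxw18 (-1.58) negative ones, with limma adjusted p between 3.70e-05 and 0.0134. The calls of Trdn (2.30, in another probe set than the one given for aged RPE/choroid) and Cd5l (-1.25) ended with 9 and 2 of 16 single arrays left out (limma adjusted p up to 0.0672 and 0.0628). The terms of Trdn were positive in all 19 probe sets and passed in 2, not including the brightest (2.05, limma adjusted p = 0.0557). Without the male arrays the calls of Catspere2, Olfr1372-ps1, Mir680-2, Fbxw18 and Cd5l ended, and those of H2-M2, Ctse and Trdn held. The count was 20 without RPE/choroid aged WT replicate 3, 25 without RPE/choroid aged Cfh-/- replicate 2, 6 without dim probe sets, 8 without the male arrays and 40 with array weights. In young mice limma called 0 probe sets, with 1260 at an unadjusted p under 0.05, and 1 to 3 with a single RPE/choroid array left out (1 without WT replicate 2, 3 without WT replicate 3, 3 without Cfh-/- replicate 1 and 2 without Cfh-/- replicate 3) and 9 with array weights. The smallest p belonged to Gabra5 (0.98), Hspa1l (1.15) and Edem1 (0.72), with Gfap (-1.72) also in the first 10.

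The dissections were compared in young WT mice. Neuroretina held more of the neuronal genes Rit2, a small GTPase (4.22 ± 0.36), Gabra2, a GABA receptor subunit (3.93 ± 0.31), Chrna6, a nicotinic receptor subunit (3.77 ± 0.23), and Olfm3 (3.66 ± 0.22). RPE/choroid held more of the matrix proteoglycan gene Dcn (-6.52 ± 0.22), the melanocyte and pigment genes Mlana (-6.06 ± 0.22), Tyrp1 (-6.03 ± 0.18), Pmel (-5.50 ± 0.18) and Dct (-5.35 ± 0.17), and the fast muscle troponin Tnnc2 (-5.31 ± 0.26). Limma adjusted p for these 10 genes were at most 8.63e-11. Among complement genes, Serping1 (-3.03), C3ar1 (-3.33), C1s1 (-2.45), the C1q receptor gene Cd93 (-2.44) and C1qc (-2.18) were higher in RPE/choroid, and Cd59a (2.13 ± 0.27) and Vtn, the complement-binding vitronectin (1.92), in neuroretina. In all 11926 probe sets passed, 6237 higher and 5689 lower in neuroretina.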

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

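The tests of sex and of array scaling in the pattern of aged WT arrays and the comparison with control probe sets over distinct values were chosen after the result was seen, as were the fits without male arrays and without the probe sets of that pattern.

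Some samples stood far from the other 3 of their group, by Dixon's ratio, in 8 of 96 group checks over 12 measures, where chance gives about 1 in 20. In neuroretina, aged WT replicate 1 had a mean log2 intensity of 7.03 over lens crystallins, against 6.83 to 6.86, and of 6.79 over microglia and macrophage genes, against 6.50 to 6.52. Young WT replicate 1 had 8.22 over lens crystallins, against 7.41 to 7.50. Young WT replicate 4 had 5.73 over complement receptors, against 5.54 to 5.55, 11.63 over rod photoreceptor genes, against 12.09 to 12.15, and 8.01 over RPE and visual cycle genes, against 8.24 to 8.27. Young Cfh-/- replicate 4 had 5.65 over complement receptors, against 5.48 to 5.51. In RPE/choroid, aged Cfh-/- replicate 1 had an array median of 103.5 intensity units, against 99.6 to 100.1.

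The effect of genotype differed between ages in neuroretina, by the limma interaction, for Pttg1 (3.71 on the log2 scale), Catspere2 (3.00), 5830417I10Rik (1.61), Gm10590 (0.98), Mir680-2 (-1.94), Nmnat1 (-1.50), Cerkl (-1.34), Rbp7 (-1.27) and Lyrm7 (-1.17). In RPE/choroid it differed for Pttg1 (2.59), 5830417I10Rik (1.76), Gabra5 (1.27), 1700029I15Rik (0.92), Pcdhb12 (-1.75), H2-M2 (-1.53) and Zmat2 (-0.87). In aged mice it differed between tissues, as neuroretina over RPE/choroid, for Olfr1372-ps1 (2.42), Catspere2 (2.36), Trdn (2.30), H2-M2 (1.68), Mir680-2 (-1.81), Ctse (-1.75), Fbxw18 (-1.58) and Cd5l (-1.25). Without the male arrays the calls of Catspere2 and Lyrm7 in neuroretina, of all 7 genes in RPE/choroid, and of Olfr1372-ps1, Catspere2, Mir680-2, Fbxw18 and Cd5l between tissues ended.

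In aged WT arrays 26 probe sets, of which 22 were distinct and the others copies with identical values, lay outside the range of the other 12 arrays on the same side in both tissues, against 0.0175 expected by chance and 0, 0 and 2 in young WT, young Cfh-/- and aged Cfh-/- arrays. Their 9 named genes are Pttg1, Catspere2, 5830417I10Rik, Gm10590, Nmnat1, Rbp7, Rbm46, Aga and BC051142. These probe sets supplied 24 of the 54 calls between aged genotypes in neuroretina and 21 of the 58 in RPE/choroid, or 20 of 47 and 17 of 53 with copies counted once. With age they supplied 25 of the 138 calls in WT neuroretina and 25 of the 693 in WT RPE/choroid. In Cfh-/- mice they supplied 0 of 42 and 1 of 730. The tables argue against sex, with 0 of 24 aged WT and young arrays read as male, against the Nnt difference between C57BL/6 substrains, with Nnt apart in 0 of 2 tissues, and against array scaling alone, with 25 of the 26 still apart in both tissues under quantile normalization, which kept 60 of 75 other probe sets apart in neuroretina. RNA quality stays open, since 0.0151% of control and 0.0773% of distinct tested probe sets were apart (Fisher's exact test, two-sided p = 0.105). Age in WT mice was not tested and stays open. Other alleles in the aged WT mice also stay open and may account for part of the set. Of its 8 genes with a known position, 25% had another within 10 genes against a mean of 0.714% in random sets (one-sided permutation p = 0.0282). This rests on 1 pair, Rbp7 and Nmnat1. Gm10590 and the unnamed probe sets of the set were not placed, so the test does not cover them. For Cd59a, whose aged WT neuroretina arrays also lay outside the other 12, 0 of the 40 nearest genes did so where chance gives 0.106, so a 0 was likely either way and neighbouring alleles stay open.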

How the results depend on the processing

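The fits without male arrays and without the 26 probe sets apart in aged WT arrays were chosen after the data had been seen. Of 5903 pairs of a named gene and an alternative, 5101 stayed on the same side of the threshold with the same direction, 777 lost the call, 11 gained it and 14 changed direction. These 14 were Cd59a in contrasts where it was called neither as reported nor under the alternative. Its log2 fold change turned to 0.0032 in young neuroretina between genotypes under the carry-over covariate and to 0.0279 with age in Cfh-/- RPE/choroid without the male arrays. With single arrays left out it lay between -0.11 and 0.0496 in the former, -0.10 and 0.26 with age in WT RPE/choroid, -0.37 and 0.22 in Cfh-/- RPE/choroid and -0.50 and 0.10 for the RPE/choroid interaction. Where a result changed, the cause was not tested unless stated. Signal over background was not measured, so what dim probe sets could show stays unknown.

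Under quantile normalization, an intensity trend with robust variance and a pseudocount of 16, each count of probe sets stayed within 1.5 times the reported one, as did the 10 counts within a tissue under the carry-over covariate, which was not applicable to the fit of both tissues. Other alternatives moved counts further. Leaving out dim probe sets, which tests fewer, gave 2 in young neuroretina between genotypes and 6 for the aged genotype by tissue interaction. Fitting the compared groups alone, which leaves fewer arrays for the spread, was not applicable to interactions and gave 35 in aged neuroretina and 2 in young RPE/choroid between genotypes, and with age 76 in WT neuroretina, 431 in WT and 470 in Cfh-/- RPE/choroid. Array weights gave 128 in aged neuroretina between genotypes, 455 and 168 with age in WT and Cfh-/- neuroretina, 1138 with age in Cfh-/- RPE/choroid, 61 and 29 for the genotype by age interactions of neuroretina and RPE/choroid, and 9 and 40 for the young and aged genotype by tissue interactions. Without the male arrays the counts were 34 and 14 in aged neuroretina and RPE/choroid between genotypes, 20 and 13 with age in Cfh-/- neuroretina and RPE/choroid, 12 and 8 for the interactions with age and 8 for the aged interaction with tissue. This leaves 2 aged Cfh-/- neuroretina arrays and 1 RPE/choroid array, whose spread is taken from the other groups. Without the 26 probe sets they were 27 and 26 between aged genotypes in neuroretina and RPE/choroid, and 2 and 0 for the interactions with age, where limma had 1011 and 2137 at an unadjusted p under 0.05 with these kept.

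With an estimated correlation 0 lists were called by camera in the 8 contrasts other than age in RPE/choroid, with 1 to 6 at an unadjusted p under 0.05, and with age in RPE/choroid 8 were called in WT and 6 in Cfh-/- mice. With single arrays left out, the lowest and highest counts of probe sets were 3 and 4 in young and 37 and 64 in aged neuroretina between genotypes, 81 (without young replicate 3) and 163 with age in WT and 25 (without young replicate 2) and 40 in Cfh-/- neuroretina, 15 and 26 for its interaction, 3 and 6 in young and 32 (without aged WT replicate 4) and 58 in aged RPE/choroid between genotypes, 407 (without aged replicate 1) and 649 with age in WT and 338 (without aged replicate 4) and 570 in Cfh-/- RPE/choroid, 10 (without aged Cfh-/- replicate 3) and 19 for its interaction, 0 and 3 for the young interaction with tissue, 9 and 25 (without RPE/choroid aged Cfh-/- replicate 2) for the aged one, and 10830 and 12072 between tissues. For lists they were, in the same order within a tissue, 3 and 8, 3 and 12, 7 and 14, 2 and 10, 3 and 7 in neuroretina and 6 and 13, 8 and 14, 19 and 23, 13 and 20, 4 and 13 in RPE/choroid. Direction reversed without male arrays for 3 lists between aged genotypes in RPE/choroid, oxidative stress response (camera adjusted p = 0.562), heat shock and unfolded protein response (0.953) and cholesterol and lipid metabolism (0.697). It reversed for rod photoreceptor genes with age in WT RPE/choroid without young WT replicate 4 (camera adjusted p = 0.868, with 2.55e-05 the lowest with an array left out) and for lens crystallins in the RPE/choroid interaction without young Cfh-/- replicate 4 (0.893, lowest 3.31e-05).

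Samples share replicate numbers. Deviations of same-numbered samples of different groups correlated above 0.1 in 9 of 24 pairs in neuroretina, with values from -0.68 to 0.65, and in 2 of 24 in RPE/choroid. Differently numbered pairs were not compared, so whether the numbers pair samples within a tissue stays open. Pairing across tissues was not tested, but aged Cfh-/- replicate 4 read as female in neuroretina and male in RPE/choroid, so that number does not mark the same mouse. With the replicate number as a block no count moved beyond 1.5 times, with 45 probe sets called between genotypes in aged neuroretina, 635 with age in WT and 567 in Cfh-/- RPE/choroid, and 39 calls of named genes ended.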

Other observations

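The tests of genes on the chromosome of Cfh, with any set of genes, and the test of male mice in the ageing pattern were chosen after the results were seen.

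Further gene groups moved with age in RPE/choroid. Cytokines and chemokines lay higher in WT (camera adjusted p = 2.40e-05, adjusted p = 0.0418 with an estimated correlation) and in Cfh-/- mice (camera adjusted p = 6.33e-06, adjusted p = 0.0347 with an estimated correlation), with 3 of 23 members rising in each and 6 and 7 adjusted over the list alone. Examples are Cxcl13, a B cell attractant, in WT (1.14) and Ccl2, a monocyte attractant, in Cfh-/- mice (0.85). Senescence genes lay higher in WT (camera adjusted p = 0.0026, adjusted p = 0.0418 with an estimated correlation) and in Cfh-/- mice (camera adjusted p = 0.0118, adjusted p = 0.0711 with an estimated correlation), and 2 of 9 members rose in each genotype, Mmp3 and the macrophage elastase Mmp12 (2.05 in WT and 1.49 in Cfh-/-), proteases that macrophages and fibroblasts secrete; adjusted over the list alone 2 and 3 rose. Mast cell genes lay higher in WT (camera adjusted p = 0.000959, adjusted p = 0.0418 with an estimated correlation), where 2 of 9 rose and 1 fell, and 3 and 1 adjusted over the list alone, with the mast cell carboxypeptidase Cpa3 at 1.69 ± 0.21 (limma adjusted p = 0.000304). Oxidative phosphorylation genes lay lower in WT (camera adjusted p = 0.000579, adjusted p = 0.403 with an estimated correlation), with none of 22 past the threshold over all genes in limma and 5 lower adjusted over the list alone. Circadian clock genes lay lower in both genotypes. In WT the camera adjusted p was 0.0106, with adjusted p = 0.154 with an estimated correlation, and of 16 members 1 fell over all genes and 1 rose and 4 fell adjusted over the list alone. Of the 16 2 fell in Cfh-/- mice, among them the clock repressor Nr1d1 (-0.66), and 1 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.00361, adjusted p = 0.115 with an estimated correlation).

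MHC class I genes lay higher with age in WT (camera adjusted p = 0.00298, adjusted p = 0.142 with an estimated correlation) and Cfh-/- RPE/choroid (camera adjusted p = 0.000284, adjusted p = 0.0662 with an estimated correlation), with 1 and 2 of 11 members rising, and 3 and 3 adjusted over the list alone. Interferon response genes lay higher too (camera adjusted p = 0.00019 in WT and 0.000319 in Cfh-/- mice, adjusted p = 0.278 and 0.349 with an estimated correlation), with Ifit1, an RNA-binding antiviral gene, the 1 of 19 past the threshold in each (0.98 and 0.75), and 3 and 1 adjusted over the list alone. The Ifit1 call in Cfh-/- mice ended with 7 of 8 single arrays left out (limma adjusted p up to 0.133). Fibroblast and matrix genes lay higher in Cfh-/- mice (camera adjusted p = 0.0134, adjusted p = 0.349 with an estimated correlation), with 3 of 17 rising, among them Dcn (0.49) and the calcification inhibitor Mgp (0.62), and 5 rising and 1 falling adjusted over the list alone. Endothelial genes lay higher in Cfh-/- mice too (camera adjusted p = 0.0186, adjusted p = 0.404 with an estimated correlation), with 1 of 14 rising and 4 rising and 1 falling adjusted over the list alone. That list's call ended without the male arrays (camera adjusted p = 0.0593), as did, in limma, the call of each gene given here for Cfh-/- mice apart from Mmp3. Cone photoreceptor genes lay lower with age in WT RPE/choroid (camera adjusted p = 0.00278, adjusted p = 0.403 with an estimated correlation), with none of 13 past the threshold over all genes in limma and 3 lower adjusted over the list alone. Over the 10 contrasts within a tissue, camera called lists 95 times at the preset correlation and 14 times with an estimated one, of which 8 in WT and 6 in Cfh-/- RPE/choroid with age. The lists called in none of the 10 contrasts were the chromosome 1 neighbours of Cfh (lowest camera adjusted p = 0.0749), pericyte and smooth muscle (0.0715), cornea and conjunctiva (0.174), ciliary body and iris (0.0721), immunoglobulin (0.286) and orthologues of risk genes of macular degeneration (0.0718).

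Genes lower in Cfh-/- mice may be alleles carried along with the targeted locus, which the tests leave open. Of the genes called at both ages within a tissue, Mcm6 and Dbi, 100% of 2 lie on the chromosome of Cfh, which holds 5.65% of the tested genes (one-sided exact binomial p = 0.0032), but this restates on 2 genes what had prompted the test. Both genes called between young genotypes in neuroretina, Mcm6 and Arpc5, lie there too (p = 0.0032), and the other set, genes called in both tissues for the mean of both ages with the aged WT set left out, held 1 gene, Mcm6 (exact binomial p = 0.0565). Mcm6, Dbi and Arpc5 lie 121, 148 and 31 genes from Cfh among the 1126 measured on that chromosome, and the list of its neighbours was called in none of the 10 contrasts (lowest camera adjusted p = 0.0749). That list test asks for a shared direction, so it cannot exclude carried alleles that raise some genes and lower others. Genes called only between aged genotypes, Ctse among them, were not placed on the chromosome. With 3 genes over overlapping sets, all of which lie on that chromosome, carried alleles and an effect of the loss of factor H protein cannot be told apart.

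The rise of macrophage and complement genes in aged RPE/choroid may reflect more macrophages, more transcript per macrophage or a change in the dissection. A lower share of lens or retina RNA would raise other cell types alike, and the median log2 change of macrophage genes exceeded that of endothelial, fibroblast, melanin and RPE genes by at least 0.512. That is just above the 0.5 set for the test, and with a lowest bootstrap bound of 0.0107 it argues against this explanation by a narrow margin, for these lists only. Skeletal muscle genes were not compared, and the muscle gene Trdn rose with age in WT (3.34), so a change in the share of muscle in the dissection stays open. Male mice are argued against as the cause in WT, where the macrophage list rose and all arrays read as female (camera adjusted p = 1.34e-12). That test was made on the macrophage list alone. It does not cover Cfh-/- mice, where 3 of 4 aged RPE/choroid arrays read as male. The median change of the 20 macrophage genes in WT, 0.621, does not separate cell number from transcript per cell, which cannot be told apart in whole tissue, and age itself stays open, untested.

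Other splits of the arrays were counted for each comparison, the real one included. For probe sets with age, 1 of 35 splits gave as many as the real 138 in WT neuroretina (highest other 32), the 42 in Cfh-/- neuroretina (0), the 693 in WT RPE/choroid (1) and the 730 in Cfh-/- RPE/choroid (3), so chance can be excluded at 0.05 for each taken alone. These shares were not adjusted over the comparisons, and 1 of 35 is the smallest that such splits can give. The same 1 of 35 held for the 4 of young neuroretina (0) and the 58 of aged RPE/choroid (0) between genotypes and the 11926 between tissues (5708). For genotype in aged neuroretina 2 of 35 splits reached 54 (highest other 213) and in young RPE/choroid 2 of 35 reached 4 (64), so chance cannot be excluded there. For the interactions 100 splits were drawn. Of these 3 reached the 21 of genotype by age in neuroretina (25), 2 the 16 in RPE/choroid (28) and 3 the 13 of genotype by tissue in aged mice (61). Those shares lie under the 0.05 set beforehand. They argue against chance for each interaction taken alone, before any adjustment over the comparisons. Other splits called more probe sets than the real one, so chance is not excluded outright. In young mice 100 of 100 reached the 0 that limma called for genotype by tissue (5), where 1260 had an unadjusted p under 0.05, so chance cannot be excluded there either. The splits with 213, 64 and 61 probe sets, several times the real count, may reflect a structure of the samples other than the groups, which was not tested.

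For the number of lists, chance can be excluded for the 21 in WT RPE/choroid with age, reached by 1 of 35 splits (highest other 19). It cannot be excluded for the other 9 contrasts. In neuroretina 27 of 35 reached the 4 between young genotypes (13), 16 of 35 the 5 between aged genotypes (12), 4 of 35 the 10 with age in WT (16), 21 of 35 the 5 with age in Cfh-/- mice (11) and 39 of 100 the 6 of the interaction (13). In RPE/choroid 15 of 35 reached the 10 between young genotypes (18), 4 of 35 the 9 between aged genotypes (11), 3 of 35 the 16 with age in Cfh-/- mice (16) and 30 of 100 the 9 of the interaction (17).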
